A study of Mus musculus with 77 samples.

How the data were processed

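The 77 libraries came from mouse cerebral white matter and, per the labels, carry a cell type (EC, pericyte, OPC, astrocyte or microglia) and a condition (control or stroke). Per the labels, RNA was taken with the NucleoSpin RNA XS kit and libraries were made with the Takara SMART-Seq v4 kit. The values are deposited counts of reads per Ensembl gene, in 5 tables of 52636 genes each, with no normalization and 1 column per library. Per the submitters' processing notes, reads were processed with bcl2fastq 2.20, STAR and HTSeq against GRCm38. The versions of STAR and HTSeq, the annotation release and the handling of strands and mates are not given in the sources used here. Column names begin with "hisat" in 4 of the 5 tables although the processing notes list STAR. How the cells were isolated, what P2 and P4 mean, and what EC and OPC abbreviate are not given in the sources used here.

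The kit gives unstranded reads, so antisense transcripts and overlapping genes cannot be told apart, and no molecular identifiers, so intervals and floors computed from counts cover counting error only. Library totals ran from 43367636 to 142944063 in the EC, pericyte, OPC and astrocyte tables and from 5530125 to 11770194 in microglia. Each count table used all of its columns. Gene symbols were joined to Ensembl identifiers. Genes without a symbol numbered 233 and held at most 0.0545% of the counts of any library, and 147 genes shared a symbol. The 37 mitochondrial genes had 0 counts in all libraries, so that the list of mitochondrial genes could not be tested in any table.

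Groups were taken from the labels: control and stroke within each of EC, pericytes, OPC and astrocytes, and P2 control, P2 stroke and P4 stroke in microglia, 11 groups in all. Stroke was compared with control within each cell type, and P4 stroke with P2 stroke, as P4 has no control. The comparisons, tests, thresholds, gene lists, ligand and receptor pairs and the rule for naming genes were chosen before the data were examined, and the alternatives said to be added were chosen after seeing the data. Library numbers were disjoint between control and stroke within a cell type, so that no pairing was used.

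Each comparison was fitted on its own table with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors and genes kept by filterByExpr. P-values were adjusted by the Benjamini-Hochberg method, and genes under an adjusted p of 0.05 were called. Fold changes are on the log2 scale with standard errors from the fit, and group levels are means and SD of CPM, with TMM-scaled library totals in both levels and bounds. A gene with 0 counts in a group was given a lower bound against 3 counts over the group, and a gene with 1 to 3 counts a ratio with its 95% counting interval. The direction in single libraries was counted against the median of the other group.

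Lists were 13 of marker genes (endothelial, pericyte, smooth muscle, fibroblast, astrocyte, OPC, mature oligodendrocyte, microglia, monocyte and border macrophage, neutrophil, lymphocyte, neuron, ependymal and choroid plexus) and 15 of pathways (cell cycle, interferon response, antigen presentation, cytokines, chemokines and adhesion, disease-associated microglia, reactive astrocyte, extracellular matrix and TGF-beta, angiogenesis, blood-brain barrier, oligodendrocyte differentiation and myelin, cholesterol synthesis, hypoxia and glycolysis, immediate early, unfolded protein and stress response, mitochondrial). They were written from general knowledge. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, and adjusted over the lists of a comparison. The alternatives were a correlation estimated for each list and the rotation test fry. Member genes were also adjusted over the list alone.

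Genes were named by a rule. It took the 8 largest increases and 8 largest decreases past the threshold with a mean of at least 10 CPM in the higher group, leaving out predicted genes and pseudogenes. It took up to 3 called members of each pathway list by p, or 1 if none was called, 2 members of each called marker list of another cell type, and the first 3 detected markers of the library's own type. It also took the 8 pathway genes with the smallest interaction p, up to 5 called ligand or receptor genes, and Serpine2, Lrp1, Entpd1 and Adora3. Of these the report prints a part, and some genes that the rule took are not reported here. Genes of the fit without microglia and the genes changed in all 4 cell types were named after their values were seen.

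The interaction of cell type and condition was fitted over all 5 tables with edgeR, with P4 libraries left out (68 libraries). After seeing the data, the fit was repeated on the 4 tables without microglia (51 libraries), and the 4 separate fits were compared by a chi-square test of heterogeneity. Overlap of called genes was compared with the number expected from independent lists among genes tested in both tables. A receptor counted as detected at 1 CPM or more in at least 3 in 4 libraries of the stroke group, or at 5 CPM as the alternative. Closeness of libraries was measured as the mean chi-square per gene over genes with at least 20 summed counts in a pair.

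Alternatives chosen beforehand were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, a filter of 1 read in 2 libraries, a filter of 10 CPM, 1 surrogate variable from sva 3.50.0, each library left out in turn, and P2 and P4 stroke libraries together. Added alternatives were library totals alone, the mean of the microglia markers as a covariate, classes of library number or depth as a covariate and each class alone, pericyte control 11 and 15 summed, and fits without libraries singled out by ependymal markers, Malat1, astrocyte markers or few detected genes. Libraries were regrouped at random with a fixed seed, 100 groupings in each comparison and 22 for each interaction fit, the real one included.

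The tests were tested on simulated counts, drawn gene by gene from the means, spreads and library totals of the real libraries. Chosen genes were changed, and correlation between genes was not simulated. Of 100 genes changed 4-fold the test recovered 80 in EC, 58 in pericytes, 93 in OPC, 76 in astrocytes and 2 in each microglia comparison, and of 100 changed 2-fold it recovered 48, 25, 70, 44 and 0. Other genes called numbered 3 to 6 in the first 4 tables and 0 in microglia. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.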

Results

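RNA of mouse cerebral white matter was measured in 77 libraries, each labelled with 1 of 5 cell types (EC, pericyte, OPC, astrocyte or microglia) and with control or stroke. The labels do not expand EC and OPC. Marker genes of endothelial cells and of oligodendrocyte precursor cells were used for them here. There were 5 control and 7 stroke libraries of EC, 7 and 8 of pericytes, 6 and 6 of OPC, and 6 and 6 of astrocytes. Microglia libraries carried a further label, P2 or P4, which the labels do not explain, and comprised 8 P2 control, 9 P2 stroke and 9 P4 stroke libraries. Total counts per library were 57569368 to 142944063 in EC, 47422629 to 77948299 in pericytes, 54752585 to 71292806 in OPC, 43367636 to 64557642 in astrocytes and 5530125 to 11770194 in microglia. Genes with at least 10 counts numbered 17503 to 24329 per library in the first 4 tables and 5876 to 14243 in microglia. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. The closest pair of libraries was pericyte control 11 and 15 (mean chi-square per gene 15.8, next closest pericyte pair 92.3). The labels do not say whether they are separate samples, and they were kept as 2 libraries (6227 genes called, 5026 with both summed).

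The libraries held RNA of several cell types, and some of it moved with the condition. Marker genes were summed per library, in CPM (counts scaled to a common library total). Astrocyte markers reached 36848 ± 6485 CPM (SD, n = 6) in astrocyte control libraries and 757 ± 117 CPM (n = 6) in OPC controls. The 14 endothelial markers reached 4495 ± 1008 CPM (n = 5) in EC controls and 597 CPM in pericyte controls, while mature oligodendrocyte markers in the same EC controls reached 13576 ± 3387 CPM and neuron markers 8669 ± 1324 CPM. OPC control libraries carried 102967 ± 3552 CPM of mature oligodendrocyte markers against 11773 ± 520 CPM of OPC markers. Microglia markers were higher in stroke than in control libraries of each of these 4 cell types, at 199 ± 39.9 against 109.5 ± 16.0 CPM in EC and 2716 ± 551 against 920.1 ± 482 CPM in pericytes. In OPC they stood at 632 ± 193 against 111 ± 26.3 CPM, and in astrocytes at 1478 ± 241 against 552 ± 67.2 CPM. Levels were set side by side across tables that were counted and scaled separately.

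**Figure D1:**
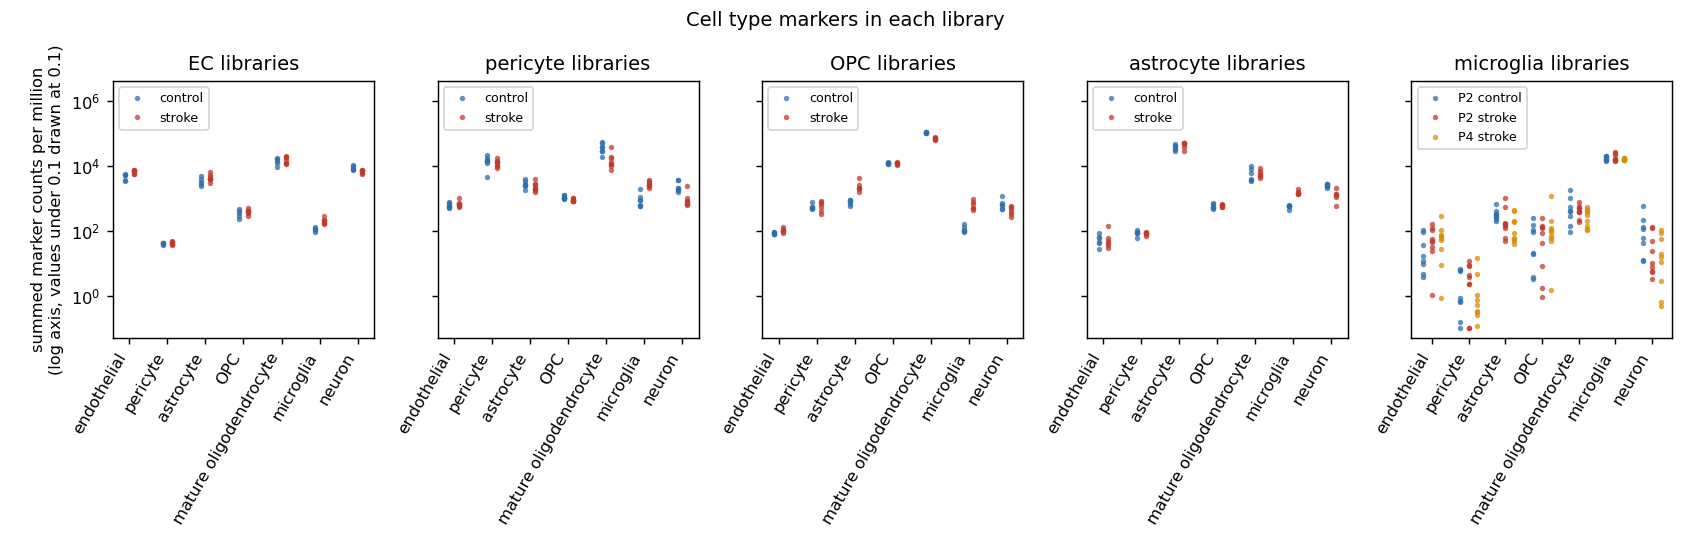
Summed CPM of the marker genes of 7 cell types in each library, on a log axis, with 1 point per library, 1 panel per table and colours for the groups. Microglia markers averaged 111 CPM in OPC control and 632 CPM in OPC stroke libraries.

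In EC libraries, the interferon and cytokine lists rose after stroke and the cholesterol synthesis list fell. Ubd, a ubiquitin-like protein induced by interferon gamma, stood at 67.9 ± 45.4 CPM (SD, n = 7) in stroke and 7.53 ± 5.77 CPM (n = 5) in control. This 8.96-fold difference was seen in 6 of 7 stroke libraries (edgeR quasi-likelihood adjusted p = 0.0206). Cxcl9, an interferon-induced chemokine, was 6.51-fold higher, in 7 of 7 libraries (adjusted p = 0.0153). Fdft1, which makes squalene, fell by 0.57 on the log2 scale (SE 0.06), from 173 ± 6.58 to 116 ± 5.86 CPM, in 7 of 7 libraries (adjusted p = 0.00289). On GRCm38, Ubd (ENSMUSG00000035186, protein coding) lies on chromosome 17 at 37193892 to 37196095 on the + strand, and Fdft1 (ENSMUSG00000021273, protein coding) on chromosome 14 at 63145150 to 63179578 on the - strand. Scgb3a1, Adam8, Lilr4b, Ms4a7, Gpnmb and Lrg1 were 4.09-fold to 6.37-fold higher. Besides immunoglobulin genes, the largest decreases were those of Cdh6 (log2 fold change -0.95), Mas1 (-0.77), Insig1 (-0.74), Car10 (-0.72), Rgs4 (-0.70) and Slc6a7 (-0.70). The immunoglobulin genes Ighv1-82 and Igkv4-59 had log2 fold changes of -7.75 and -6.56, each from 1 control library: the values were 0.10 without control 7 and -0.87 without control 11.

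Of the 20 interferon response genes, 18 rose, 0 fell and 2 did not pass in EC, and 20 were higher when adjusted over the list alone (camera adjusted p = 8.44e-18). Irf7, a transcription factor of the interferon response, rose with a log2 fold change of 0.95 ± 0.13 (SE), and Isg15 with 0.69 ± 0.13. Of 18 antigen presentation genes 11 rose and 7 did not pass (17 higher adjusted over the list alone, camera adjusted p = 8.18e-12, adjusted p = 0.0954 with an estimated correlation). Among them were the peptide transporter genes Tap1 (0.81) and Tap2 (0.59) and the class I gene H2-K1 (0.72). Of 20 cytokine, chemokine and adhesion genes 7 rose and 13 did not pass (11 adjusted over the list alone, camera adjusted p = 5.83e-08), including Cxcl10 (0.99), Ccl2 (1.15) and the leukocyte adhesion receptor Selp (3.73 ± 0.71). Of 21 genes of the disease-associated microglia list 13 rose and 8 did not pass (15 adjusted over the list alone, camera adjusted p = 1.11e-14), among them Lgals3 (1.58), Spp1 (1.06) and Ch25h (1.69). Microglia markers moved with these groups: 5 of 12 rose and 7 did not pass (10 adjusted over the list alone, median log2 fold change 0.71, camera adjusted p = 6.72e-08). Monocyte and border macrophage markers were called too (4 of 10 higher, 4 adjusted over the list alone, camera adjusted p = 0.00754, adjusted p = 0.154 with an estimated correlation).

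Among 21 extracellular matrix and TGF-beta genes in EC, 9 rose and 12 did not pass (11 adjusted over the list alone, camera adjusted p = 6.72e-08). Col4a1 rose by 0.76, Tgfb1 by 0.97 and Sparc by 0.85. Fibroblast markers moved alongside (2 of 10 higher, 3 adjusted over the list alone, camera adjusted p = 0.00754, adjusted p = 0.0532 with an estimated correlation). Of 23 cell cycle genes 5 rose and 18 did not pass (11 adjusted over the list alone, camera adjusted p = 2.45e-07, adjusted p = 0.0928 with an estimated correlation), with Top2a at 2.63 ± 0.38. In the reactive astrocyte list 6 of 15 rose and 9 did not pass (11 adjusted over the list alone, camera adjusted p = 1.35e-07, adjusted p = 0.0958 with an estimated correlation). Among them were Vim (0.75) and Osmr (0.74), which other cells also express. Endothelial markers rose in 5 of 14 and did not pass in 9 (9 adjusted over the list alone, camera adjusted p = 3.01e-08, adjusted p = 0.0958 with an estimated correlation). The tight junction gene Cldn5 rose by 0.67 ± 0.17, whereas Pecam1 (0.43, adjusted p = 0.0997) and Flt1 (0.42, adjusted p = 0.114) did not pass. Of 18 blood-brain barrier genes 3 rose (Cldn5, Tjp1 and Lsr) and 15 did not pass (8 adjusted over the list alone, camera adjusted p = 5.76e-05, adjusted p = 0.217 with an estimated correlation). Of 18 angiogenesis genes 2 rose (Adm and Aplnr) and 16 did not pass (4 adjusted over the list alone, camera adjusted p = 0.000159, adjusted p = 0.0958 with an estimated correlation).

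Cholesterol synthesis genes were lower in EC stroke libraries: 7 of 19 fell and 12 did not pass (14 lower adjusted over the list alone, median log2 fold change -0.40, camera adjusted p = 8.18e-12). They included Fdft1 and Msmo1 (-0.47), an enzyme of sterol demethylation. Neuron markers moved with them: 6 of 12 fell and 6 did not pass (9 adjusted over the list alone, camera adjusted p = 3.26e-08, adjusted p = 0.0958 with an estimated correlation), with Snap25 at -0.55 and Syt1 at -0.47. Ependymal markers (1 of 8 higher, 4 adjusted over the list alone, camera adjusted p = 0.000522, adjusted p = 0.161 with an estimated correlation) were called higher. So were astrocyte markers (0 of 12 passed, 0 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.596 with an estimated correlation). Oligodendrocyte differentiation and myelin genes were also called (2 of 18 higher, Itpr2 and Tcf7l2, 2 adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.62 with an estimated correlation). Camera did not call hypoxia and glycolysis (3 of 16 higher, with 4 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.99). Nor did it call immediate early genes (1 of 19 higher, Ier3, 1 adjusted over the list alone, 0.305) or the unfolded protein list (0 of 15, 2 adjusted over the list alone, 0.397). Among markers it did not call pericyte (1 of 12 higher, 1 adjusted over the list alone, 0.311), smooth muscle (0.233), OPC (0.435), mature oligodendrocyte (0.181) and lymphocyte (0.999) markers in EC.

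In all, 1309 of 20995 genes passed in EC, 749 higher and 560 lower, and the values of stroke and control libraries did not overlap for 809 genes (3.85%, against 0.253% by chance). With library totals alone as scaling the split was 940 higher and 254 lower, 78.7% higher in place of 57.2%, and the median of all genes moved to 0.102. The EC libraries fell into a class numbered up to 6 and a class above 6 that differed in depth, and edgeR called 0 genes within either (1748 and 4156 genes at an unadjusted p under 0.05), with a correlation of log2 fold changes of 0.31 between the classes. With the depth class as a covariate the count was 1054, and 1021 of the 1309 genes were among them. The count was 138 without control 7, 195 without control 9, 625 without stroke 8 and 748 without stroke 10. In turn, 33 and 28 of the gene calls taken by the naming rule, Ubd and Cxcl9 included, ended without control 7 and control 9.

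In pericyte libraries, hypoxia, extracellular matrix, cytokine and cell cycle genes were higher after stroke, and myelin, cholesterol and neuronal genes were lower. Camera called 19 lists there, and 0 of them with an estimated correlation. Mmp9, which degrades type IV collagen and gelatin, stood at 1800 ± 801 CPM (SD, n = 8) in stroke and 1.02 ± 1.56 CPM (n = 7) in control. Its log2 fold change was 10.81 ± 1.09 (SE), higher in 8 of 8 libraries (edgeR adjusted p = 1.29e-05). Serpinb2, an inhibitor of plasminogen activators, reached 13.5 ± 10.6 CPM against 0 counts in control, at least 1930-fold higher against a floor of 3 counts over the control group, in 7 of 8 libraries (adjusted p = 0.000611). Fcho1 showed the largest decrease, from 287 ± 300 to 34.6 ± 23.3 CPM (log2 fold change -3.05 ± 0.58), lower in 8 of 8 libraries (adjusted p = 0.00141). On GRCm38, Mmp9 (ENSMUSG00000017737, protein coding) lies on chromosome 2 at 164940780 to 164955850 on the + strand. Serpinb2 (ENSMUSG00000062345, protein coding) lies on chromosome 1 at 107511423 to 107535478 on the + strand and Fcho1 (ENSMUSG00000070000, protein coding) on chromosome 8 at 71708387 to 71725716 on the - strand. Mmp12 (9.24), Mmp10 (9.00), Saa3 (8.11), Hp (7.77) and Nipal1 (7.68) followed on the log2 scale, and Mmp1b was higher by a ratio of 4550 with a counting interval of 817 to 180000. Tac1 (-2.18 ± 0.31), Rgs9 (-2.17), Gpr6 (-2.45), Rxrg (-2.20), Kcnh4 (-2.13) and Actn2 (-2.08) were lower. The decrease of Neb (-2.74, adjusted p = 0.0481) did not pass without control 11 (-2.24) or control 15 (-2.26), nor without 9 other libraries left out singly.

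Of 16 hypoxia and glycolysis genes 15 rose and 1 did not pass in pericytes (15 adjusted over the list alone, median 1.58, camera adjusted p = 2.2e-12, adjusted p = 0.113 with an estimated correlation). Egln3, a prolyl hydroxylase that marks HIF for degradation, rose 11.7-fold from 3.69 ± 1.73 to 43.1 ± 13.2 CPM, Hk2, a hexokinase, 12.2-fold, and Ero1l, an oxidase of the endoplasmic reticulum, 5.97-fold, each in 8 of 8 libraries. Of 17 angiogenesis genes 9 rose and 8 did not pass (10 adjusted over the list alone, camera adjusted p = 8.05e-05, adjusted p = 0.113 with an estimated correlation), with Vegfa at 1.26 ± 0.20 and Adm at 1.75. Of 15 unfolded protein and stress response genes 10 rose, 1 fell and 4 did not pass (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.97e-05, adjusted p = 0.155 with an estimated correlation). Sdf2l1 stood at 1.77 and Atf4 at 0.72. Of 19 immediate early genes 9 rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.178 with an estimated correlation), with Egr2 at 2.83 and Junb at 1.93.

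In the extracellular matrix list 16 of 21 genes rose and 5 did not pass (17 adjusted over the list alone, median 2.09, camera adjusted p = 1.19e-11, adjusted p = 0.123 with an estimated correlation). They included fibronectin, Fn1, at 4.94 ± 0.56, and the collagen genes Col3a1 at 3.44 and Col1a2 at 2.39. Fibroblast markers moved with them (5 of 10 higher, 5 not passed, 5 adjusted over the list alone, camera adjusted p = 0.000992, adjusted p = 0.207 with an estimated correlation). Their sum was 13300 ± 5228 CPM in stroke against 4555 ± 1762 CPM in control. Of the pericyte's own markers 2 of 12 rose and 10 did not pass (1 adjusted over the list alone, camera adjusted p = 0.244). Pdgfrb was higher by 0.53 ± 0.18 (adjusted p = 0.0374), a call that ended without any 1 of 11 libraries, with values of 0.42 to 0.55. Rgs5 (0.15 ± 0.26, adjusted p = 0.704) and Kcnj8 (0.33, adjusted p = 0.375) did not pass. Smooth muscle (2 of 8 higher, 2 adjusted over the list alone, camera adjusted p = 0.244), ependymal (0 of 8, 0.496) and endothelial markers (3 higher, 2 lower, 9 not passed of 14, 0.496) were not called.

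Inflammatory lists rose in pericytes. Of 21 cytokine, chemokine and adhesion genes 15 rose and 6 did not pass (17 adjusted over the list alone, median 2.76, camera adjusted p = 2.89e-10, adjusted p = 0.113 with an estimated correlation). Among the chemokine genes were Ccl7 at 4.53 ± 0.39, Cxcl1 at 6.14 and Ccl2 at 3.69. Of 21 disease-associated microglia genes 17 rose and 4 did not pass (19 adjusted over the list alone, median 2.67, camera adjusted p = 5.12e-14, adjusted p = 0.123 with an estimated correlation). Spp1, osteopontin, went from 893 ± 755 to 12600 ± 3800 CPM, and Ctsb and Lgals3 were 5.07-fold and 13.9-fold higher. Microglia markers moved with these (10 of 12 higher, 2 not passed, 11 adjusted over the list alone, median 1.68, camera adjusted p = 6.44e-08, adjusted p = 0.123 with an estimated correlation). So did neutrophil markers (3 of 3 higher, 3 adjusted over the list alone, camera adjusted p = 0.00309, adjusted p = 0.113 with an estimated correlation), at 132 ± 58.1 against 30.5 ± 24.4 CPM. Monocyte markers were called too (3 of 11, 3 adjusted over the list alone, 0.013, adjusted p = 0.169 with an estimated correlation). Interferon response genes rose in 19 of 20 (1 not passed, 20 adjusted over the list alone, camera adjusted p = 2.2e-12, adjusted p = 0.127 with an estimated correlation), with Usp18 at 2.02. Antigen presentation genes rose in 13 of 18 (5 not passed, 14 adjusted over the list alone, 3.9e-07, adjusted p = 0.178 with an estimated correlation). Cell cycle genes rose in 22 of 23 (1 not passed, 23 adjusted over the list alone, 2.12e-13, adjusted p = 0.127 with an estimated correlation), with Cdk1 12.0-fold higher. Reactive astrocyte genes rose in 9 of 15 (6 not passed, 9 adjusted over the list alone, 1.55e-06, adjusted p = 0.113 with an estimated correlation), with Vim at 2.53.

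Myelin genes fell in pericyte stroke libraries. In the oligodendrocyte differentiation list 14 of 18 fell and 4 did not pass (15 adjusted over the list alone, median -1.08, camera adjusted p = 9.81e-08, adjusted p = 0.129 with an estimated correlation), with the myelin protein gene Mog at -1.31 ± 0.21. Mature oligodendrocyte markers fell in 9 of 12 (3 not passed, 11 adjusted over the list alone, 3.64e-07, adjusted p = 0.127 with an estimated correlation), from 36002 ± 12550 to 15552 ± 9244 CPM. Neuron markers fell in 9 of 12 (3 not passed, 11 adjusted over the list alone, 1.26e-05, adjusted p = 0.178 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 19 (7 not passed, 13 adjusted over the list alone, 4.68e-05, adjusted p = 0.178 with an estimated correlation), with Lss at -1.01. The blood-brain barrier list was not called (4 higher, 3 lower, 11 not passed of 18, 4 and 4 adjusted over the list alone, median -0.24, camera direction up, adjusted p = 0.762), though Slc2a1, the brain glucose transporter, rose 2.95-fold. OPC (1 higher, 4 lower of 12, adjusted p = 0.185), astrocyte (1 higher, 2 lower of 12, 0.496) and lymphocyte markers (1 higher, 1 lower of 9, 0.496) were not called.

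Altogether 6227 of 21694 genes passed in pericytes, 3440 higher and 2787 lower, and the groups did not overlap for 1187 genes (5.47%, against 0.0311% by chance). With library totals alone the split was 2573 higher and 4198 lower, 38% higher in place of 55.2%, and the median of all genes was -0.28 (-0.08 with TMM, -0.12 with RLE size factors), against which these changes are to be read. Libraries numbered up to 10 gave 953 genes (752 higher, 201 lower) and those above 10 gave 7959, with a correlation of log2 fold changes of 0.75 between the classes. Of genes called in 1 class and tested in the other, 941 of 944 and 7512 of 7822 had the same direction there. With the number class as a covariate the count was 7864.

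In OPC libraries, microglial, interferon, matrix and astrocyte genes were higher after stroke and myelin genes lower. Mmp10 and Mmp13, secreted matrix metalloproteinases, had 0 counts in the 6 control libraries and reached 20.6 ± 12.8 and 14.1 ± 7.20 CPM (SD, n = 6) in stroke. They were at least 2450-fold and at least 1700-fold higher, in 6 of 6 libraries (edgeR adjusted p = 5.33e-06 and 1.57e-05). Mog fell from 1740 ± 163 to 828 ± 57.3 CPM (log2 fold change -1.07 ± 0.07 SE, lower in 6 of 6, adjusted p = 3.17e-07). Penk, the enkephalin precursor of neurons, fell from 53.1 ± 6.99 to 15.0 ± 9.68 CPM (-1.82 ± 0.31, 6 of 6, adjusted p = 0.000642). On GRCm38, Mmp10 (ENSMUSG00000047562, protein coding) lies on chromosome 9 at 7502352 to 7510240 on the + strand. Mmp13 (ENSMUSG00000050578, protein coding) lies on the same chromosome at 7272514 to 7283331 on the + strand and Mog (ENSMUSG00000076439, protein coding) on chromosome 17 at 37010743 to 37023398 on the - strand. Mmp9 (7.69), Mmp12 (7.61), Cxcl10 (6.30 ± 0.63), Col4a6 (6.04), Tgm1 (5.96) and Ptx3 (5.82) followed. The decrease of Ttr, a choroid plexus gene, rested on control 11 (-5.50, but -2.15 and not passed without it), and Sst, Fam163b, Cck, Nrgn and Neurod6 fell by 1.32 to 1.71 on the log2 scale.

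Myelin and mature oligodendrocyte genes fell in OPC libraries: 12 of 12 mature markers (12 adjusted over the list alone, median -0.81, camera adjusted p = 7.9e-16). So did 11 of 18 differentiation and myelin genes, with 1 higher and 6 not passed (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 6.15e-07, adjusted p = 0.143 with an estimated correlation). Opalin, a membrane protein gene of myelinating oligodendrocytes, fell by 1.23 ± 0.11 (SE) and Ermn by 1.10. The OPC markers were not called (1 higher, 1 lower, 10 not passed of 12, 1 and 1 adjusted over the list alone, median 0.04, adjusted p = 0.928). Pdgfra stood at 0.09 ± 0.12 (adjusted p = 0.65), Cspg4 at 0.17 (0.253) and Vcan at 0.11 (0.459). Cholesterol synthesis genes fell in 14 of 19 (5 not passed, 17 adjusted over the list alone, camera adjusted p = 2.11e-11, adjusted p = 0.12 with an estimated correlation), with Msmo1 at -0.79. Neuron markers fell with them in 7 of 12 (5 not passed, 9 adjusted over the list alone, 0.000156, adjusted p = 0.301 with an estimated correlation).

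The disease-associated microglia list rose in 18 of 21 genes in OPC libraries (3 not passed, 19 adjusted over the list alone, median 3.26, camera adjusted p = 1.34e-19), with the lysosomal gene Cd68 19.1-fold and Ctsd 3.22-fold higher. Microglia markers rose in 12 of 12 (12 adjusted over the list alone, median 2.49, camera adjusted p = 3.14e-14, adjusted p = 0.0543 with an estimated correlation), with Fcrls 19.5-fold higher. Monocyte markers rose in 4 of 7 (3 not passed, 4 higher and 1 lower adjusted over the list alone, 0.00122, adjusted p = 0.0543 with an estimated correlation). Astrocyte markers rose in 9 of 12 (3 not passed, 9 adjusted over the list alone, 4.33e-06, adjusted p = 0.12 with an estimated correlation), from 757 ± 117 to 2356 ± 966 CPM. Gfap was 11.5-fold and the water channel gene Aqp4 10.5-fold higher. Reactive astrocyte genes rose in 12 of 15 (3 not passed, 15 adjusted over the list alone, 3.44e-11), with Cd44 at 5.45. Interferon genes rose in 20 of 20 (20 adjusted over the list alone, 1.73e-16, adjusted p = 0.12 with an estimated correlation), with Isg15 at 4.24 ± 0.43. Antigen presentation genes rose in 17 of 18 (1 not passed, 18 adjusted over the list alone, 1.56e-15, adjusted p = 0.117 with an estimated correlation), with Psmb9 at 3.17. Cytokines rose in 12 of 14 (2 not passed, 12 adjusted over the list alone, 2.81e-11), with Ccl2 at 4.32.

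Extracellular matrix genes rose in 17 of 21 in OPC libraries (1 fell, 3 not passed, 18 and 1 adjusted over the list alone, camera adjusted p = 1.04e-10), with Col3a1 25.9-fold higher. Fibroblast markers moved with them (6 higher, 1 lower, 2 not passed of 9, 6 and 1 adjusted over the list alone, 0.00122, adjusted p = 0.12 with an estimated correlation), at 85.3 against 19.7 CPM. Cell cycle genes rose in 16 of 23 (7 not passed, 20 adjusted over the list alone, 9.08e-09, adjusted p = 0.12 with an estimated correlation), with Mki67 at 1.45 ± 0.17. The hypoxia list was not called (3 higher, 4 lower, 9 not passed of 16, 4 and 4 adjusted over the list alone, adjusted p = 0.593): Hk2 rose by 1.70, whereas Ndrg1 (-0.87) and Bnip3 (-0.58) fell. Among immediate early genes 3 rose and 3 fell of 19 (4 and 3 adjusted over the list alone, median -0.03, camera direction up, adjusted p = 0.708), with Fos at 2.87 ± 0.33 and Atf3 at 4.01. Angiogenesis (5 higher, 3 lower of 16, 6 and 3 adjusted over the list alone, 0.465), blood-brain barrier (2 and 2 of 18, 2 and 2 adjusted over the list alone, 0.503) and unfolded protein genes (2 and 2 of 15, 3 and 2 adjusted over the list alone, 0.928) were not called. Nor were endothelial (3 higher of 13, 0.465), pericyte (1 lower of 12, 0.805), smooth muscle (2 higher of 6, 0.511), ependymal (2 lower of 7, 0.134) and lymphocyte markers (1 and 1 of 3, median -0.86, mean 0.39, camera direction down, 0.867).

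In OPC 3726 of 18167 genes passed, 2133 higher and 1593 lower, and the groups did not overlap for 2016 genes (11.1%, against 0.216% by chance). With library totals alone the split was 3347 higher and 804 lower, 80.6% higher in place of 57.2%, with the median of all genes at 0.106. With a filter of 10 CPM the count was 2421 among 9907 tested genes.

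In astrocyte libraries, microglial, interferon and cell cycle genes were higher after stroke and neuronal genes lower, while the astrocyte markers were not called. Ch25h, cholesterol 25-hydroxylase, went from 0.483 ± 0.367 to 19.2 ± 8.46 CPM (SD, n = 6 each; log2 fold change 5.29 ± 0.52 SE, higher in 6 of 6, edgeR adjusted p = 2.36e-05). Cst7, a cathepsin inhibitor, rose 15.6-fold (adjusted p = 2.23e-06) and Ms4a7, a macrophage membrane protein gene, 30.5-fold (adjusted p = 5.05e-06), each in 6 of 6. Penk fell by 1.85 ± 0.16, from 276 ± 70.6 to 76.3 ± 8.60 CPM, in 6 of 6 libraries (adjusted p = 9.8e-06). On GRCm38, Ch25h (ENSMUSG00000050370, protein coding) lies on chromosome 19 at 34473778 to 34475164 on the - strand and Penk (ENSMUSG00000045573, protein coding) on chromosome 4 at 4133531 to 4138819 on the - strand. Lilr4b (4.84), Lilrb4a (4.01), Ifi27l2a (3.96), Ifi207 (3.92) and Cd72 (3.88) were higher. Cd4 (-2.26), Scn4b (-2.07), Gpr6 (-2.05), Tac1 (-1.96) and Rem2 (-1.82) were lower.

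The disease-associated microglia list rose in 17 of 21 genes in astrocyte libraries (4 not passed, 18 adjusted over the list alone, median 1.99, camera adjusted p = 6.1e-23), with Cd68 6.72-fold and Trem2, a microglial receptor, 4.89-fold higher. Microglia markers rose in 11 of 12 (1 not passed, 11 adjusted over the list alone, median 1.40, camera adjusted p = 2.42e-19), with Fcrls 7.88-fold higher. Monocyte markers rose in 6 of 8 (1 fell, 1 not passed, 6 and 1 adjusted over the list alone, 0.000168). Interferon genes rose in 18 of 20 (2 not passed, 20 adjusted over the list alone, 7.2e-26), with the antiviral synthetase gene Oas1a at 2.89 ± 0.18. Antigen presentation genes rose in 11 of 18 (7 not passed, 14 adjusted over the list alone, 4.69e-13), with H2-DMb1 at 2.15. Cytokines rose in 8 of 17 (9 not passed, 8 adjusted over the list alone, 6.84e-07), with Ccl3 at 3.00 and Ccl4 at 2.64. Cell cycle genes rose in 13 of 23 (10 not passed, 17 adjusted over the list alone, 1.98e-14), with Cdk1 5.54-fold higher.

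Of the astrocyte markers 0 of 12 passed, also adjusted over the list alone (median -0.04, camera adjusted p = 0.954), and Gfap stood at 24000 ± 7470 against 17000 ± 6030 CPM (0.50 ± 0.26, adjusted p = 0.285). Reactive astrocyte genes rose in 5 of 15 (10 not passed, 7 adjusted over the list alone, 6.84e-07, adjusted p = 0.238 with an estimated correlation), with the intermediate filament genes Vim at 1.33 ± 0.20 and Nes at 1.28. Extracellular matrix genes rose in 11 of 21 (1 fell, 9 not passed, 12 and 1 adjusted over the list alone, 5.17e-06), with Col3a1 at 4.40. Fibroblast markers moved beside them (4 of 9 higher, 5 not passed, 6 adjusted over the list alone, 0.000943), as did smooth muscle markers (2 of 7 higher, 5 not passed, 3 adjusted over the list alone, 0.0119, adjusted p = 0.276 with an estimated correlation). Neuron markers fell in 9 of 12 (3 not passed, 12 adjusted over the list alone, camera adjusted p = 7.39e-10, adjusted p = 0.0651 with an estimated correlation), from 2500 ± 253 to 1263 ± 460 CPM. The activity-regulated genes Egr1 (-1.09) and Nr4a1 (-1.21) fell in a list that was not called (1 higher, 2 lower of 19, 3 and 3 adjusted over the list alone, adjusted p = 0.37). Not called either were cholesterol synthesis (0 of 19, 0 adjusted over the list alone, 0.0947) and hypoxia (2 higher of 16, 2 adjusted over the list alone, 0.577, with Hk2 at 1.75). Nor were angiogenesis (2 higher of 17, 3 adjusted over the list alone, 0.456), blood-brain barrier (0 of 18, 0.956), myelin (0 of 18, 0.805) and unfolded protein genes (1 higher and 1 lower of 15, 1 and 1 adjusted over the list alone, 0.956). Among markers of other types, not called were endothelial (0 of 13, 0.954), pericyte (1 higher of 12, 0.336), OPC (1 lower of 12, 0.954), mature oligodendrocyte (0 of 12, 0.517), ependymal (1 higher of 8, 0.184) and lymphocyte markers (1 lower of 4, 0.954).

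In astrocytes 1939 of 18796 genes passed, 1059 higher and 880 lower, and the groups did not overlap for 1387 genes (7.38%, against 0.216% by chance). Libraries numbered up to 8 gave 2499 genes and the 4 libraries above 8 gave 233, with a correlation of log2 fold changes of 0.70 between the classes. Of genes called in 1 class and tested in the other, 2437 of 2481 and 232 of 232 had the same direction. With the number class as a covariate the count was 2480. The count was 3521 with 1 surrogate variable and 1271 with a filter of 10 CPM.

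**Figure D2:**
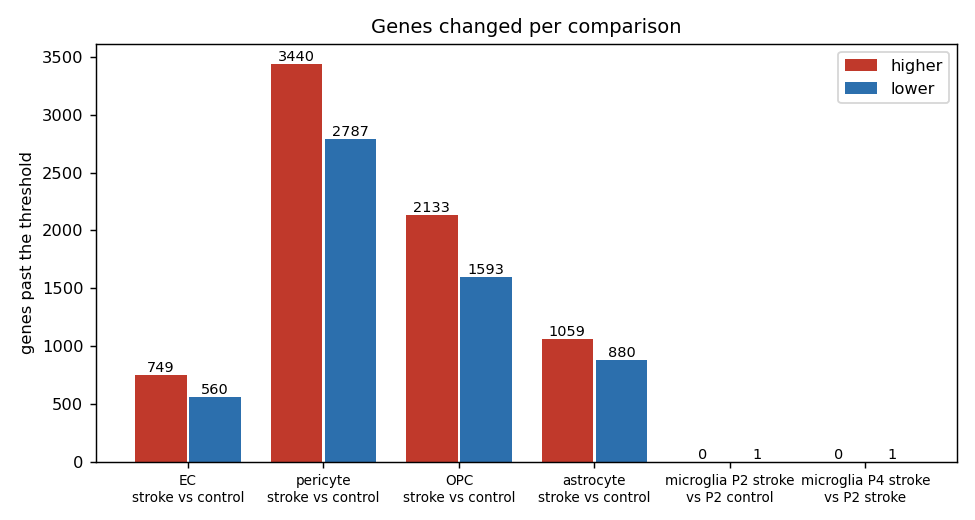
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood) in each of 6 comparisons, with a bar for genes higher and a bar for genes lower. Pericytes had the most, with 3440 higher and 2787 lower, and each microglia comparison had 1.

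**Figure D3:**
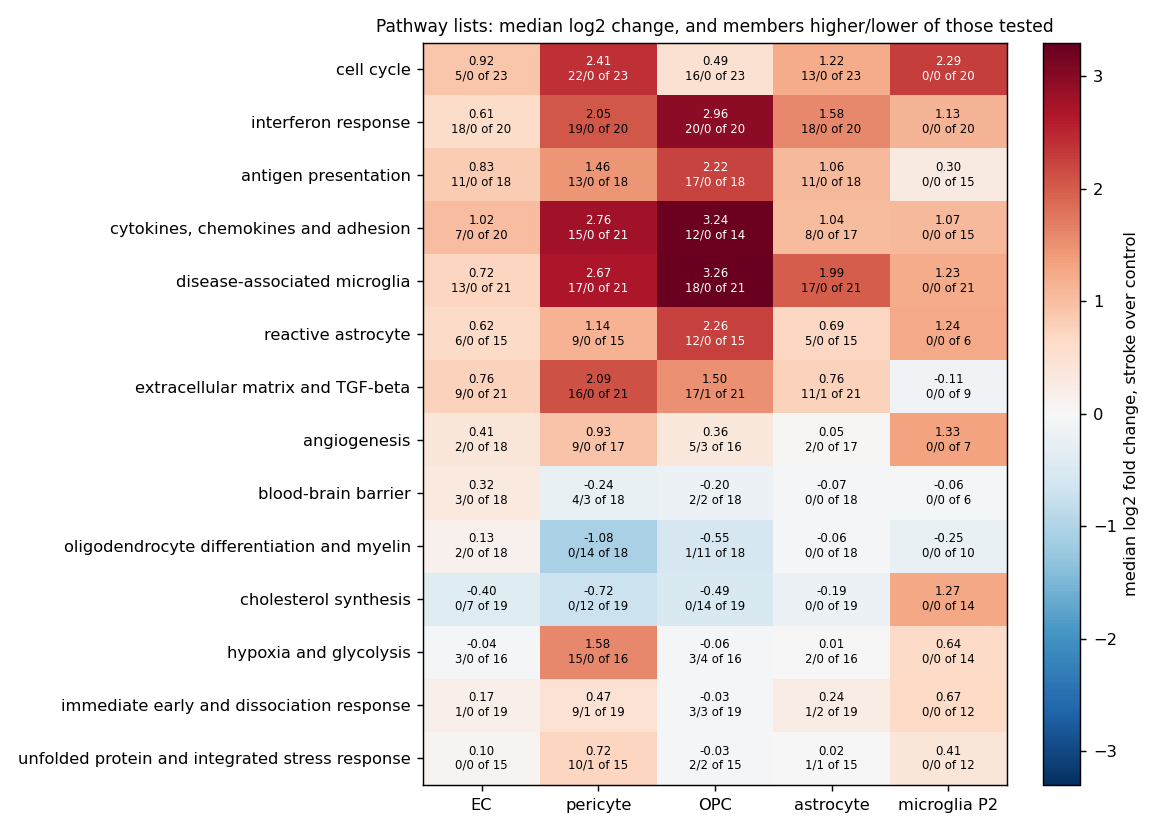
Median log2 fold change, stroke against control, of 14 pathway lists in 5 cell types, with the members higher and lower of those tested. The disease-associated microglia list had medians of 0.72 in EC, 2.67 in pericytes, 3.26 in OPC and 1.99 in astrocytes, and hypoxia and glycolysis had -0.04, 1.58, -0.06 and 0.01.

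In P2 microglia libraries, only Preb passed when stroke was compared with control. Preb, a regulator of vesicle export from the endoplasmic reticulum, stood at 46.2 ± 32.4 CPM (SD, n = 9) in stroke and 4620 ± 8430 CPM (n = 8) in control. Its log2 fold change was -6.64 ± 1.17 (SE, lower in 9 of 9, edgeR adjusted p = 0.0294). It lies on chromosome 5 of GRCm38 at 30950853 to 30960361 on the - strand (ENSMUSG00000045302, protein coding). Camera called the disease-associated microglia list higher (0 of 21 passed, 8 higher adjusted over the list alone, median 1.23, camera adjusted p = 1.77e-18, adjusted p = 0.0439 with an estimated correlation). The lysosomal protease gene Ctsd stood at 1.11 ± 0.26 (9 of 9 libraries higher, adjusted p = 0.134). Cell cycle genes (0 of 20 passed, 2 adjusted over the list alone, median 2.29, camera adjusted p = 2.31e-14, adjusted p = 0.115 with an estimated correlation) were called too. So were interferon genes (0 of 20, 0 adjusted over the list alone, median 1.13, 3.47e-08, adjusted p = 0.349 with an estimated correlation). Also called were antigen presentation (0 of 15, 0 adjusted over the list alone, median 0.30, 0.00439), cytokines (0 of 15, 1 adjusted over the list alone, median 1.07, 0.0292) and reactive astrocyte genes (0 of 6, 0 adjusted over the list alone, median 1.24, 0.0141), each with adjusted p = 0.349 with an estimated correlation. Microglia markers were not called (0 of 12, median 0.21, camera direction down, adjusted p = 0.863), with P2ry12 at 0.36 ± 0.32 (adjusted p = 0.721), Tmem119 at 0.11 (0.952) and Cx3cr1 at 0.17 (0.93).

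In the same comparison no member of the other tested lists passed and camera called none of them. Among markers these were endothelial (median 1.57, adjusted p = 0.173), smooth muscle (0.37, 0.513), astrocyte (0.98, camera direction down, 0.229), OPC (0.94, 0.284), mature oligodendrocyte (-0.55, camera direction up, 0.38) and neuron (-1.80, 0.173). Among pathways they were extracellular matrix (-0.11, 0.38), angiogenesis (1.33, 0.254), blood-brain barrier (-0.06, 0.863), myelin (-0.25, 0.513), cholesterol synthesis (1.27, 0.368), hypoxia (0.64, 0.103), immediate early (0.67, 0.248) and unfolded protein genes (0.41, 0.103). At an unadjusted p under 0.05 there were 1342 of 13225 genes, against 661 by chance, DESeq2 called 158 genes and limma voom 53, in both cases without Preb. The edgeR count was 15 without control 12 and 0 without control 3, control 7 or any 1 of the 9 stroke libraries.

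P4 stroke libraries were compared with P2 stroke libraries, since P4 has no control. Only Gpr165, an orphan receptor gene on the X chromosome at 96713441 to 96719388 on the + strand of GRCm38 (ENSMUSG00000031210, protein coding), passed. It stood at 0.191 ± 0.188 CPM (SD, n = 9) in P4 and 62.9 ± 106 CPM (n = 9) in P2 (log2 fold change -8.29 ± 1.37 SE, lower in 9 of 9, edgeR adjusted p = 0.0106). Camera called interferon genes (0 of 20 passed, median 0.91, adjusted p = 9.69e-10, adjusted p = 0.199 with an estimated correlation) and antigen presentation (0 of 15, 0.62, 7.28e-05, adjusted p = 0.169 with an estimated correlation) higher in P4. It also called the disease-associated microglia list (0 of 21, 0.84, 9.69e-10, adjusted p = 0.145 with an estimated correlation) and extracellular matrix (0 of 9, 0.39, 0.00608, adjusted p = 0.0806 with an estimated correlation) higher in P4, with 0 members of each adjusted over the list alone. It called myelin genes (0 of 10, median -0.82, 0.000661, adjusted p = 0.11 with an estimated correlation) and mature oligodendrocyte markers (0 of 9, -0.73, 0.00721, adjusted p = 0.196 with an estimated correlation) lower. The phagocytic receptor gene Axl stood at 2.31 ± 0.79 (9 of 9 libraries higher, adjusted p = 0.233). P2ry12 stood at -1.0 ± 0.31 (9 of 9 lower, adjusted p = 0.196) and Tmem119 at -1.03 (0.281), while 3 of 12 microglia markers were lower adjusted over the list alone. Camera did not call the microglia (median -0.25, adjusted p = 0.673), endothelial (0.83), smooth muscle (0.664), astrocyte (0.189), OPC (0.664) or neuron markers (0.83). Nor did it call cell cycle (0.153), cytokines (0.129), reactive astrocyte (0.863), angiogenesis (0.765), blood-brain barrier (0.664), cholesterol synthesis (0.863), hypoxia (0.478), immediate early (0.217) or unfolded protein genes (0.129). DESeq2 called 145 genes, with Gpr165 among them, and limma voom 0, with 1517 at an unadjusted p under 0.05 in edgeR. The edgeR count was 3 without P2 stroke 17, and 2 without P2 stroke 2, 11 or 15 or P4 stroke 19.

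Whether the stroke effect differed among cell types was tested as an interaction. Among genes of the pathway lists, 3 hypoxia genes had the smallest p. Ero1l had log2 fold changes of -0.26 in EC, 2.51 in pericytes, -0.04 in OPC and -0.19 in astrocytes (edgeR interaction adjusted p = 1.95e-10). Egln3 had values of -0.19, 3.49, 0.55 and -0.01 (1.95e-10) and Bnip3, a mitophagy receptor gene, of -0.31, 1.61, -0.59 and -0.28 (1.95e-10). Egr2 (2.94e-09), Slc2a1 (3.41e-08) and the glycolysis genes Pgk1 (1.49e-07) and Eno1 (1.74e-07) had their highest values in pericytes, at 2.77, 1.49, 1.54 and 1.14. Fos had 2.87 in OPC against 0.13 in EC, 0.16 in pericytes and 0.14 in astrocytes (4.54e-08), and Gfap 3.53 in OPC against 0.41, 0.48 and 0.45 (1.34e-05). These values come from a fit of the 4 tables without microglia, chosen after seeing the data, in which 3619 of 25257 genes differed. In the fit of 5 tables Ero1l (adjusted p = 0.0156), Egln3 (0.00432), Eno1 (0.00412) and Fos (0.000352) passed, whereas Bnip3 (0.149), Egr2 (0.0737), Slc2a1 (0.0816), Pgk1 (0.337) and Gfap (0.378) did not. Gfap is itself an astrocyte marker, and astrocyte markers were higher in OPC stroke libraries (2356 ± 966 against 757 ± 117 CPM). Its difference cannot be told from one in astrocyte RNA.

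The test planned over all 5 tables gave 3498 of 26646 genes. Random regroupings of its libraries called 1797 to 2405 genes, and in simulated data it recovered 33 of 200 genes changed 4-fold while calling 570 others, against 120 recovered and 22 others without microglia. The 2 fits shared 1107 genes. The 8 genes of the pathway lists with the smallest p in the 5-table fit included Trem2 (adjusted p = 9.2e-06, and 0.000614 without microglia), Hk2 (1.53e-05 and 2.68e-05), Unc5b (4e-05 and 1.93e-05) and Cd68 (4.7e-05 and 0.00786). They also included Loxl2 (9.73e-05 and 0.000713), Tyrobp (0.000268 and 0.0197), Cdc20 (0.000313 and 0.00779) and Fos (0.000352 and 4.54e-08). Trem2 had 1.01 in EC, 2.63 in pericytes, 3.93 in OPC and 2.23 in astrocytes. The microglia markers rose in the same order, with medians of 0.71, 1.68, 2.49 and 1.4. For Trem2, Cd68 and Tyrobp, all on the disease-associated microglia list, a differing response cannot be told from differing amounts of microglial RNA. Between pairs of cell types in the 4-table fit, 3354 genes differed between EC and pericytes, 2798 between pericytes and OPC, 1623 between pericytes and astrocytes, 596 between EC and OPC, 360 between OPC and astrocytes and 12 between EC and astrocytes. In the 5-table fit the same pairs gave 105, 86, 51, 109, 17 and 0 genes.

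**Figure D4:**
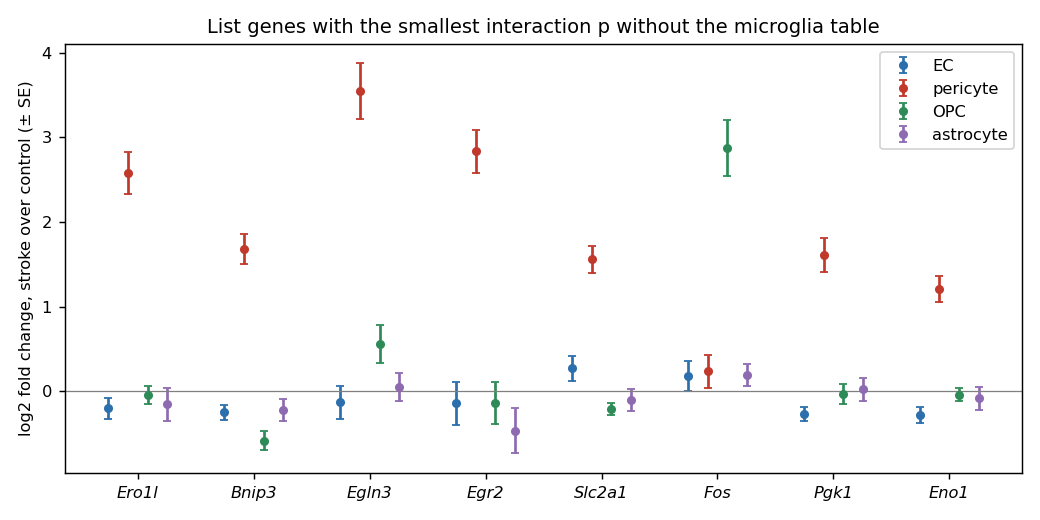
Log2 fold change, stroke against control, with its standard error, of 8 genes, as estimated in the fit of each table alone. Among genes of the pathway lists these had the smallest interaction p in the fit without microglia. Ero1l, Egln3 and Bnip3 were highest in pericytes and Fos was highest in OPC.

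**Figure D5:**
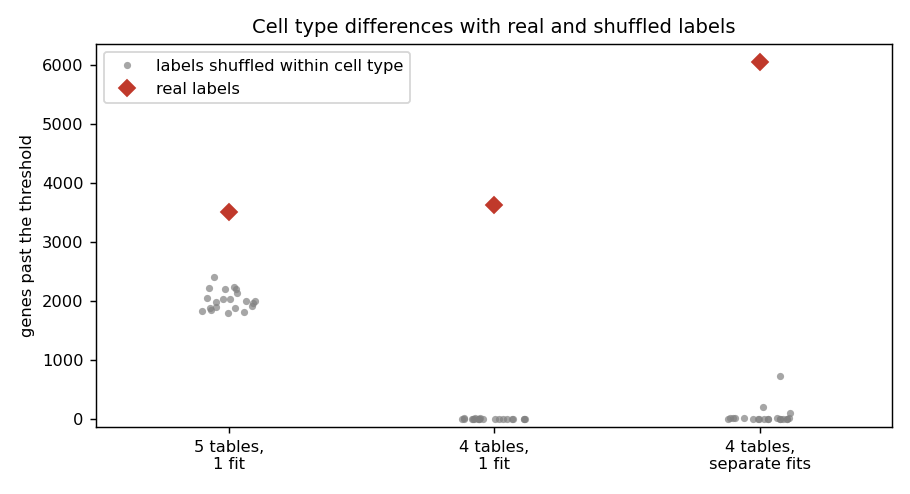
Number of genes with a differing stroke effect in the real grouping and in random regroupings of the libraries, for the 5-table fit, the 4-table fit and 4 separate fits. The real counts were 3498, 3619 and 6046.

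Genes changed in 1 cell type were changed in the others more often than chance gives. Of 17191 genes tested in all 4 tables without microglia, 313 were higher in all 4 (0.92 expected from independent lists) and 99 lower in all 4 (0.385 expected). Among those higher were the macrophage elastase gene Mmp12, with log2 fold changes of 4.22 in EC, 9.24 in pericytes, 7.61 in OPC and 3.62 in astrocytes, and the scavenger receptor gene Msr1, with 3.71, 3.32, 6.11 and 4.11. The synaptic vesicle gene Syt5 was lower in all 4, at -0.42, -0.98, -0.83 and -0.95. Pairwise, EC and astrocytes shared 406 higher genes against 40.9 expected and 278 lower against 26.5. OPC and astrocytes shared 768 higher against 123.6, EC and OPC 468 against 84.0, pericytes and astrocytes 804 against 183.8, EC and pericytes 495 against 124.6, and pericytes and OPC 1184 against 385.8. The tables share no control libraries, and microglia markers were higher after stroke in each of the 4 cell types.

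Ligand and receptor genes of 63 pairs fixed in advance were followed. In OPC 56 of 98 tested genes changed (60 adjusted over the list alone), in pericytes 55 of 105 (61), in astrocytes 32 of 102 (35), in EC 24 of 105 (43) and in P2 microglia 0 of 64 (2). Serpine2, which encodes protease nexin-1, a ligand of Lrp1, rose 4.34-fold in pericytes, from 469 ± 422 to 2030 ± 523 CPM (SD, n = 7 and 8, higher in 8 of 8, edgeR adjusted p = 0.00319). It stood at 0.32 in EC (adjusted p = 0.32), -0.02 in OPC (0.88), 0.08 in astrocytes (0.791) and 1.31 in P2 microglia (0.338) on the log2 scale. The receptor gene Lrp1 was higher by 0.70 ± 0.22 in pericytes (adjusted p = 0.0234) and stood at 0.14 in EC (0.736), 0.34 in OPC (0.103), -0.40 in astrocytes (0.668) and 0.41 in P2 microglia (0.63). The pericyte call of Lrp1 ended without control 11, control 15, stroke 7 or stroke 12 (0.60 to 0.63). Fibroblast and microglia markers rose there too, so which cells carried the Serpine2 and Lrp1 rises cannot be told. Entpd1, an ectonucleotidase that degrades ATP, was higher by 0.65 ± 0.14 in EC (adjusted p = 0.0211), 0.93 ± 0.31 in pericytes (0.0353) and 0.72 ± 0.13 in OPC (0.00123). It stood at 0.27 in astrocytes (0.206) and -0.71 in P2 microglia (0.601). The EC call of Entpd1 ended without control 7 or 9, and the pericyte call ended without any 1 of 7 libraries, with values of 0.84 to 0.89. Adora3, an adenosine receptor gene, was higher by 1.70 ± 0.37 in pericytes (0.0037) and 2.83 ± 0.68 in OPC (0.00795), and stood at 0.52 in EC (0.547), 1.40 in astrocytes (0.141) and -0.62 in P2 microglia (0.833). With the microglia markers, higher in these libraries, as a covariate (chosen after seeing the data), neither gene was called in EC, pericytes or OPC. Entpd1 then stood at 0.55 in EC (adjusted p = 0.986), -0.52 in pericytes (0.563) and -0.07 in OPC (0.962), and Adora3 at -0.06 in pericytes (0.972) and -3.19 in OPC (0.274). With this covariate edgeR called 0 genes in EC, 29 in pericytes and 442 in OPC. Stroke shared 75.5%, 76% and 91.3% of the marker variance in these tables. The lost calls therefore cannot tell microglial RNA from a response of the named cells.

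Pairs with a higher ligand in 1 cell type and a higher receptor in another numbered 21 from OPC to pericytes, 17 from pericytes to OPC, 12 from EC to pericytes, 12 from OPC to astrocytes, 11 from EC to OPC and 11 from astrocytes to pericytes. From EC to pericytes they included Tgfb1 and Tgfbr1 (0.97 and 1.31), Spp1 and Cd44 (1.06 and 2.43), Csf1 and Csf1r (0.46 and 2.16) and Fn1 and Itga5 (0.71 and 2.42). Csf1r is itself a microglia marker, and Spp1 and Csf1 are on the disease-associated microglia list. Microglia markers were higher after stroke in both tables, so which cells carried these changes cannot be told. In EC, pericytes, OPC and astrocytes the complement receptor gene C3ar1 was higher (2.03, 2.75, 4.13 and 2.57). So was the scavenger receptor gene Cd36 (4.11, 2.35, 4.60 and 3.84), beside microglia markers in the same libraries. Over the 20 sender and receiver combinations, 286 pairs had a higher ligand and a detected receptor at 1 CPM, and 251 at 5 CPM. Pair counts grow with the genes called per table, and no number expected by chance was computed.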

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

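Of the tests in this part, those with the microglia markers as a covariate, those on dilution, on mature oligodendrocyte RNA, on libraries with few detected genes and on few genes changing, and the interaction fits of 4 tables with their regroupings were chosen only after the result was seen.

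Single libraries lay far from the others of their group in summed marker CPM. Chance alone marks about 1 in 20 groups, or 3.2 of the 65 tested, and 11 were marked. Microglia markers were highest in pericyte control 8 (1920, others 550.1 to 1068) and astrocyte stroke 12 (1944, others 1292 to 1517) and lowest in astrocyte control 1 (419.4, others 556.0 to 604.0). Neuron markers were highest in pericyte stroke 3 (2372, others 629.4 to 1014), OPC control 12 (1179, others 445.3 to 696.3) and microglia P2 control 14 (577.8, others 11.44 to 211.9). Ependymal and choroid plexus markers were highest in pericyte control 6 (5205, others 69.97 to 144.8), pericyte stroke 4 (1806, others 80.71 to 737.3), OPC control 11 (275.3, others 15.77 to 25.0), microglia P2 control 12 (1.668, others 0 to 0.4469) and microglia P4 stroke 25 (1.032, others 0 to 0.3029).

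The stroke effect differed between cell types for 3498 genes in the fit of 5 tables and 3619 in the fit without microglia. How much of this comes from RNA of other cell types in the libraries was not tested. By interaction adjusted p, the 5-table fit put Trem2 (9.2e-06), Hk2 (1.53e-05), Unc5b (4e-05), Cd68 (4.7e-05), Loxl2 (9.73e-05), Tyrobp (0.000268), Cdc20 (0.000313) and Fos (0.000352) at the top of the pathway genes. The fit without microglia put Ero1l (1.95e-10), Bnip3 (1.95e-10), Egln3 (1.95e-10), Egr2 (2.94e-09), Slc2a1 (3.41e-08), Fos (4.54e-08), Pgk1 (1.49e-07) and Eno1 (1.74e-07) there. With 5 tables in the fit, 1 of 22 groupings, the real one, gave as many genes, so chance is excluded as the whole source of the count, but the other groupings reached 2405 genes, for a reason that was not tested. The highest other grouping called 6 genes without microglia, where 1 of 22 was as large, and 725 in the 4 separate fits, where 1 of 22 was as large against a real count of 6046.

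Random regroupings of the libraries within each comparison excluded chance for the counts of genes in EC (1309, highest other 4), pericytes (6227, highest other 720), OPC (3726, highest other 4) and astrocytes (1939, highest other 598), each with 1 of 100 groupings as large. The pericyte grouping with 720 genes put no library numbered above 10 in its first group and so followed the number classes, within which the real grouping gave 953 and 7959 genes. The astrocyte grouping with 598 kept 5 of the 6 stroke libraries together. For P4 against P2 stroke 3 of 100 were as large (1, highest other 6). A count of 1 gene is too small to exclude chance there. For P2 microglia 16 of 100 were as large (1, highest other 6), so that chance was not excluded. For the numbers of lists called, chance was not excluded in EC (18, highest other 19, 6 of 100 as large), pericytes (19, 21, 16 of 100), OPC (15, 16, 10 of 100), astrocytes (12, 17, 26 of 100), P2 microglia (6, 10, 23 of 100) or P4 against P2 (6, 11, 10 of 100). List by list, regroupings that gave a p as small numbered 5 or more of 100 for these called lists. In EC they were differentiation and myelin (56), astrocyte markers (51), blood-brain barrier (17), ependymal (10), monocyte (8), angiogenesis (8), fibroblast (7), cell cycle (7) and endothelial (5). In pericytes they were neuron (18), monocyte (17), cholesterol (16), antigen presentation (13), mature oligodendrocyte (10), differentiation and myelin (7), fibroblast (5) and cell cycle (5). In OPC they were neuron (18), cell cycle (6) and cholesterol (5), and in astrocytes smooth muscle (15) and reactive astrocyte (11). In P2 microglia they were cytokines (9), interferon (8), antigen presentation (7) and reactive astrocyte (5), and for P4 against P2 mature oligodendrocyte (14). The other called lists had fewer than 5 of 100, with 1 for interferon in EC, OPC and astrocytes. Regrouped tables called a median of 0 genes. They therefore do not bear on ligand and receptor genes as such (167, highest other 5, 1 of 100). Nor do they bear on whether the same genes coincide between cell types (6335 shared calls, highest other 0, 1 of 100).

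The disease-associated microglia list was higher after stroke in 4 tables, with medians of 0.72 in EC, 2.67 in pericytes, 3.26 in OPC and 1.99 in astrocytes, and scaling of the libraries is argued against, since the lowest median over 4 tables and 3 scalings was 0.72. In pericytes the median went to 0.58 (SE 0.15) with the microglia markers as a covariate, interferon response went from 2.05 to 0.94 and antigen presentation from 1.46 to 0.59, while hypoxia went from 1.58 to 1.79, extracellular matrix from 2.09 to 2.16 and mature oligodendrocyte markers from -1.07 to -1.65. More RNA of microglia in the stroke libraries may account for part of the list there, although the group shared 76% of the variance of the markers. In EC, with 75.5% shared, the median went to 0.40 (SE 0.09), between the bounds set for the test, and in OPC (1.43) and astrocytes (1.53), with 91.3% and 92.8% shared, the covariate and stroke cannot be told apart. A response of the named cells to stroke stays open.

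Mature oligodendrocyte markers fell in the OPC table (median -0.81) while OPC markers did not (median 0.04). Dilution by RNA of other cells would lower both alike, but the difference of 0.85 between the medians is the pattern itself and cannot decide. Scaling is argued against by the highest median over 3 scalings, -0.70. Less mature oligodendrocyte RNA in the stroke libraries and lower myelin gene expression in the cells cannot be told apart. The markers' log2 changes had an SD of 0.29, between the bounds set for the test. Both and dilution stay open.

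In P2 microglia 1 gene passed. Lower depth alone is argued against, since 2899 genes were still called in OPC libraries thinned to microglia totals. That table varied less between libraries (biological coefficient of variation 0.161 when thinned). Without libraries under 10000 genes the microglia coefficient was 1.17, against 1.36 with them. This argues against those libraries as the whole source of the spread. All microglia libraries had few genes with at least 10 counts (5876 to 14243, against 17503 to 24329 in the other tables). Low detection throughout the table could not be tested this way and stays open. Whether few genes change could not be told, since 2% of simulated 4-fold changes were recovered at this spread. What makes these libraries vary stays open, and no biological explanation was tested.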

How the results depend on the processing

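In this part, the tests with library totals alone, the microglia covariate, number and depth classes, summed libraries, libraries left out in sets, and the interaction over 4 tables or separate fits were chosen only after the result was seen. Of the values of named genes, 1851 kept direction and side of the threshold under alternatives chosen beforehand other than leaving out 1 library, 27 lost their call, 27 gained one and 17 reversed. With 1 library left out these numbers were 4199, 209, 8 and 20, and under added alternatives 1117, 411, 10 and 44, with 212 of the 411 from the microglia covariate. The cause was not tested where none is given below.

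Counts of called genes moved beyond 1.5 times as follows. In EC there were 2740 with DESeq2, 837 with a filter of 1 read in 2 libraries, where more genes were tested, 815 with 1 surrogate variable, and 0 with the microglia covariate in edgeR (965 at an unadjusted p under 0.05), in which stroke and the markers share most of their variance. Fewer samples were used within EC numbers up to 6 (0 in edgeR, 1748 unadjusted) and above 6 (0, 4156 unadjusted). In pericytes there were 9569 with limma voom, 29 with the microglia covariate and 953 within numbers up to 10. In OPC there were 2421 with a filter of 10 CPM, where fewer genes were tested, and 442 with the covariate. In astrocytes there were 4283 with limma voom, 1271 with the filter of 10 CPM, 3521 with 1 surrogate variable, 37 with the covariate and 233 within numbers above 8. In P2 microglia there were 158 with DESeq2, 53 with limma voom, 30 with P2 and P4 stroke libraries together and 2 without libraries under 10000 genes. Preb was among the 30 and not among the 158, 53 or 2. For P4 against P2 there were 145 with DESeq2, 0 with limma voom (828 unadjusted), 5 with the filter of 1 read in 2 libraries, 2 with the filter of 10 CPM, and 0 in edgeR without libraries under 10000 genes (742 unadjusted). For the interaction there were 9772 with limma voom, 2096 with the filter of 10 CPM and 6046 in separate fits. Lists called with an estimated correlation numbered 6 in EC, 0 in pericytes, 5 in OPC, 1 in P2 microglia and 0 for P4 against P2, and with fry 1 in P2 microglia and 0 for P4 against P2. The cause was not tested in the other cases.

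With 1 library left out, counts ranged from 138 (without control 7) to 1493 (without control 11) in EC, with 195 without control 9, 625 without stroke 8 and 748 without stroke 10. They ranged from 4942 to 7365 in pericytes, 3041 to 3936 in OPC, 1387 to 2220 in astrocytes, 0 to 15 in P2 microglia (1342 unadjusted with all libraries) and 1 to 3 for P4 against P2. P2 microglia had 0 in edgeR without control 3, control 7 or any 1 of the 9 stroke libraries and 15 without control 12. P4 against P2 had 3 without P2 stroke 17 and 2 without P2 stroke 2, 11 or 15 or P4 stroke 19.

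These log2 fold changes reversed with the microglia covariate: in EC Lilr4b -0.48, Itpr2 -0.10, Hk2 -0.33, Slc1a2 0.13 and Lrp1 -0.12; in pericytes Neb 0.69, Rgs5 -0.18, Entpd1 -0.52 and Adora3 -0.06; in OPC Lrp1 -0.55, Entpd1 -0.07 and Adora3 -3.19. In astrocytes they were Cd4 2.08, Scn4b 0.56, Ankrd63 3.53, Angpt2 -1.69, Slco1c1 0.28, Itpr2 -0.32, Idi1 0.96, Zfp36 -0.48, Asns 0.11, Sdf2l1 -0.57, Ccr2 -1.87, Gad2 0.17, Gad1 0.34 and Adora3 -3.91. The cause was not tested.

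With 1 library left out, Ighv1-82, EC stroke vs control, ranged from -9.05 to 0.10 (adjusted p = 0.983) and reversed without control 7, EC Lrp1 ranged from 0 (stroke 2) to 0.21, pericyte Rgs5 ranged from -0.07 (stroke 1) to 0.29, OPC Serpine2 went to 0.03 (control 6) and 0.01 (stroke 8), P2 microglia Tmem119 to 0 (control 8) and -0.38 (stroke 10) and Cx3cr1 to -0.15 (stroke 11), and P4 Mal ranged from -3.71 (P4 stroke 19) to 3.83. P4 Cx3cr1 fell to -0.89 without P4 stroke 19 and went to 0.05, 0.15 and 0.30 without P2 stroke 9, 10 and 11, and to 0.02, 0.11, 0.07, 0.12, 0.11, 0.06, 0.09 and 0.10 without P4 stroke 18, 20, 21, 22, 23, 24, 25 and 26. Within number classes, with fewer samples, EC Lrp1 was -0.24 (above 6), pericyte Rgs5 -0.21 and Kcnj8 -0.19 (above 10), and astrocyte Aldh1l1 -0.20 and Serpine2 -0.04 (above 8). Of these genes Ighv1-82 alone had been called with all libraries, and it rests on control 7.

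With limma voom, pericyte Rgs5 was -0.11, OPC Serpine2 0.03, astrocyte Lrp1 0.44, P2 microglia P2ry12 -0.40, Tmem119 -0.27 and Cx3cr1 -0.30, and P4 Isg15 0, Mal -0.97 and Lrp1 0.17. With 1 surrogate variable EC Lrp1 was -0.02 and P4 Mal -1.71. With library totals alone pericyte Rgs5 was -0.09 and OPC Serpine2 0.10. Rgs5 was -0.06 without the 3 pericyte libraries high in ependymal markers. OPC Serpine2 was 0 with the filter of 10 CPM and 0.02 without stroke 8 and control 11. With P2 and P4 together P2ry12 was -0.05 and Tmem119 -0.31. Without libraries under 10000 genes, P2 Slc2a1 was 0.30, P2ry12 -0.22, Tmem119 -0.35 and Cx3cr1 -0.43, and P4 Ccl4 -0.06, Stat3 -0.16, Mal -2.84, Lrp1 0.08 and Adora3 0.12. P4 Mal was -3.28 with DESeq2, and P4 Cx3cr1 was 0.15 with RLE size factors and 0 with the filter of 1 read in 2 libraries. With fry the direction reversed for hypoxia in EC (adjusted p = 0.867), lymphocyte markers in OPC (0.945) and unfolded protein genes in astrocytes (0.903). None of the results in this paragraph was called with the settings of the report, and the cause was not tested.

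No paired analysis was possible because library numbers are disjoint between control and stroke within a cell type, and the same number is control in 1 cell type and stroke in another. Sex was not added as a covariate because Xist was near 0 in all libraries, a change of pseudocount does not apply to counts, and no library had a total below the minimum set for leaving it out. At 5 CPM the ligand and receptor pairs with a detected receptor numbered 251, in place of 286 at 1 CPM. What depth limits was tested on the OPC table alone, where libraries thinned to microglia totals still gave 2899 genes.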

Other observations

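The immunoglobulin gene Ighg2c stood at 3041 ± 2285 CPM (SD, n = 5) in EC control and 2273 ± 4434 CPM (n = 7) in EC stroke libraries. The medians were 2128 and 509 CPM, and EC stroke 14 alone stood at 12236 CPM, the other stroke libraries at 51.9 to 1809 CPM. Rpl22 stood at 14362 ± 1001 CPM in EC control and 12707 ± 1834 CPM in EC stroke libraries. In control and stroke libraries it stood at 1090 and 1372 CPM in astrocytes, 36.9 and 43.2 in OPC, 39.4 and 53.6 in pericytes and 108 and 140 in P2 microglia, and at 202 in P4 stroke libraries. Malat1 stood at 2328 ± 860 CPM in pericyte control (n = 7) and 1392 ± 415 in pericyte stroke libraries (n = 8, log2 fold change -0.55, edgeR adjusted p = 0.104). In microglia it stood at 16236 ± 3323 CPM in P2 control (n = 8), 11139 ± 3882 in P2 stroke (n = 9, adjusted p = 0.747) and 8229 ± 3315 in P4 stroke libraries (n = 9, adjusted p = 0.835 against P2 stroke). The 37 mitochondrial genes had 0 counts in all 77 libraries.

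Closest pairs of libraries by mean chi-square per gene were control 7 and 9 in EC (44.6, table median 134.0), control 11 and 15 in pericytes (15.8, table median 271.6), stroke 3 and 5 in OPC (24.2, table median 50.1), control 2 and 5 in astrocytes (23.3, table median 119.4) and P2 stroke 15 and 17 in microglia (68.0, table median 256.7). With pericyte control 11 and 15 summed as 1 library, an alternative chosen after seeing the data, edgeR called 5026 genes in place of 6227.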
